A study of Mus musculus with 12 samples.

How the data were processed

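Total RNA in 12 samples of the mouse breast tumour line CCN6KOT was sequenced, 3 libraries in each of 4 groups, and the groups and replicate numbers were taken from the sample titles. The deposited table of expected counts holds estimated reads per gene, not normalised, for 55492 features, 5 of which are transgene sequences that include Cre. Cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3 and DESeq2 were used on the GRCm38 build, per the submitters' processing notes, which do not give their order or settings in the sources used here. RSEM estimates a count per gene and shares reads that map to several genes among them, so values of near-identical genes depend on that model. Whether strand was used in counting is not given in the sources used here. The deposited expected counts were already whole numbers, so rounding them changed nothing. The authors also deposited DESeq2 rlog values, which are regularised log2 counts over the 12 libraries, for 21754 genes; each gene in that table has at least 11 counts in total, and each gene left out of it has at most 10.

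Chromosome positions were taken from the GENCODE annotation of GRCm38 by Ensembl gene identifier, which matched 55141 genes. Library totals ran from 23597545 to 33999982 counts, so that a gene without a count in a library lies below 0.0882 to 0.127 CPM, from a floor of 3 counts. Replicates of a group differed by more than sampling noise in each of the 12 pairs (chi-square per degree of freedom from 2.46 to 20.7), so each library was kept as its own replicate.

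Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15052. The main test was edgeR 4.0.16 in R 4.3.3: TMM scaling, 1 fit over the 12 libraries with a mean per group, and the quasi-likelihood test for each comparison, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 12 libraries shared 1 estimate of the spread (8 residual degrees of freedom, a biological coefficient of variation of 5.17%). Levels are CPM scaled by the TMM factors. Folds against a group without counts are lower bounds from 3 counts over the group, and with 1 to 3 counts the ratio of counts is given with its 95% interval.

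Before the data were examined, 36 gene lists, the tests, the alternatives and the rule for named genes were fixed, and 33 lists were tested as sets; the other 3 had fewer than 5 tested genes or were kept for description only. Lists were tested against the other genes with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 33 lists, and again with the correlation estimated from the data. Camera called 13 lists in DNTCF4 against Vector, 15 in DNTCF4_EZH2 against DNTCF4, 17 in DNTCF4_SET against DNTCF4 and 11 between the EZH2 and SET groups; with an estimated correlation 3, 9, 12 and 6 were called. The named genes are, per comparison, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap and whose higher group has a mean of at least 1 CPM, leaving out predicted gene models. They also include the genes of the constructs and the model, up to 4 members with the smallest p of each list described, and any member of the Wnt target, Polycomb, mesenchymal and epithelial lists.

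The test was tried on simulated counts for DNTCF4 against Vector over 15052 genes, with 50 genes changed at each of 4 folds. EdgeR recovered 28 of 50 at 1.25-fold, 40 at 1.5-fold, 42 at 2-fold and 49 at 4-fold, with 15 false calls (8.6% of its calls); DESeq2 recovered 29, 39, 42 and 50, with 21 false calls (12%). A list of 30 genes raised 1.25-fold was called, and 0 of 20 random lists were. The simulated genes varied independently of each other, so this says nothing of false calls for lists whose genes vary together. The estimated correlation of the real lists reached 0.43, for ribosomal protein genes.

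The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma on the deposited rlog values, no filter on low counts, unrounded counts, the replicate number as a block, only the 6 libraries compared, a 2-fold threshold, fry in place of camera, an estimated correlation, and each library left out in turn. A filter at a mean of 1 CPM, and a fit without Vector replicate 2 and DNTCF4_SET replicate 2, which had the most receptor gene reads within their groups, were added after seeing the data, as was leaving out each Vector, DNTCF4_EZH2 or DNTCF4_SET library in turn for the genes that turned back.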

Results

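RNA-seq was made from CCN6KOT cells, a primary line from a mouse breast tumour of the spindle metaplastic type that was transduced with lentivirus and selected with puromycin. The 12 libraries fell into 4 groups of 3: cells with a control lentivirus (Vector), cells with a dominant negative TCF4 construct (DNTCF4), and cells with DNTCF4 plus a second construct labelled EZH2 (DNTCF4_EZH2) or SET (DNTCF4_SET). TCF4, encoded by Tcf7l2, is the transcription factor through which beta-catenin activates Wnt target genes, and EZH2 is the methyltransferase of the Polycomb repressive complex PRC2. The labels do not expand SET, and whether that construct carries Set, an altered EZH2 or another sequence is not given in the sources used here, so its values are those of the group as labelled. Counts on Ezh2, and not those on Set, were higher in that group than in DNTCF4, as given below. The titles of the control samples also carry the term PPGS, which is not expanded, and those of the DNTCF4 group carry the word Vector where the others name EZH2 or SET. Totals ran from 23597545 to 33999982 counts per library, and 15052 genes had enough counts to be tested. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Intervals and floors given below cover counting error only. Levels are CPM, counts scaled to library size, as mean ± SD with n = 3 per group, changes are log2 fold changes with their standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

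Ezh2 (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341, GRCm38) stood at 57.9 ± 1.53 CPM in Vector, 65.4 ± 3.1 in DNTCF4, 450 ± 20.5 in DNTCF4_EZH2 and 546 ± 33.1 in DNTCF4_SET. It was 6.88-fold higher than DNTCF4 in the EZH2 group (adjusted p = 2.03e-14) and 8.34-fold higher in the SET group (adjusted p = 1.12e-14), and the EZH2 group lay below the SET group by a log2 difference of -0.28 (SE 0.048, adjusted p = 0.003). Tcf7l2 (chromosome 19, 55741820 to 55933654) was 3.61-fold higher in DNTCF4 than in Vector, at 39.8 ± 2.41 against 11 ± 2.48 CPM (adjusted p = 1.34e-09). Counts per gene do not separate endogenous transcripts from those of a construct, and as the species and sequence of the constructs are not given, their reads may be counted on Ezh2 and Tcf7l2 only in part. Ctnnb1, which encodes beta-catenin, rose from 876 ± 9.08 CPM in Vector to 1490 ± 76.9 in DNTCF4 (adjusted p = 7.7e-11). Set was lower in DNTCF4 than in Vector by a log2 change of -0.15 (adjusted p = 0.008), a call that is lost without DNTCF4 replicate 3 (log2 change -0.12). In the SET group, where Ezh2 was higher, Set lay at 551 ± 17.2 CPM against 617 ± 43.5 in DNTCF4 (log2 -0.16, adjusted p = 0.0144, a call lost without DNTCF4_SET replicate 1 at -0.14). Between the EZH2 and SET groups Set differed by -0.04 (SE 0.045, adjusted p = 0.668). These values argue against added Set transcript in the SET group, as far as reads of such a construct would be counted on Set. Ccn6, whose name is part of the line's name, had 0 counts in 11 libraries and 1 count in DNTCF4_EZH2 replicate 1. Trp53 had at most 2 counts in any library.

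**Figure D1:**
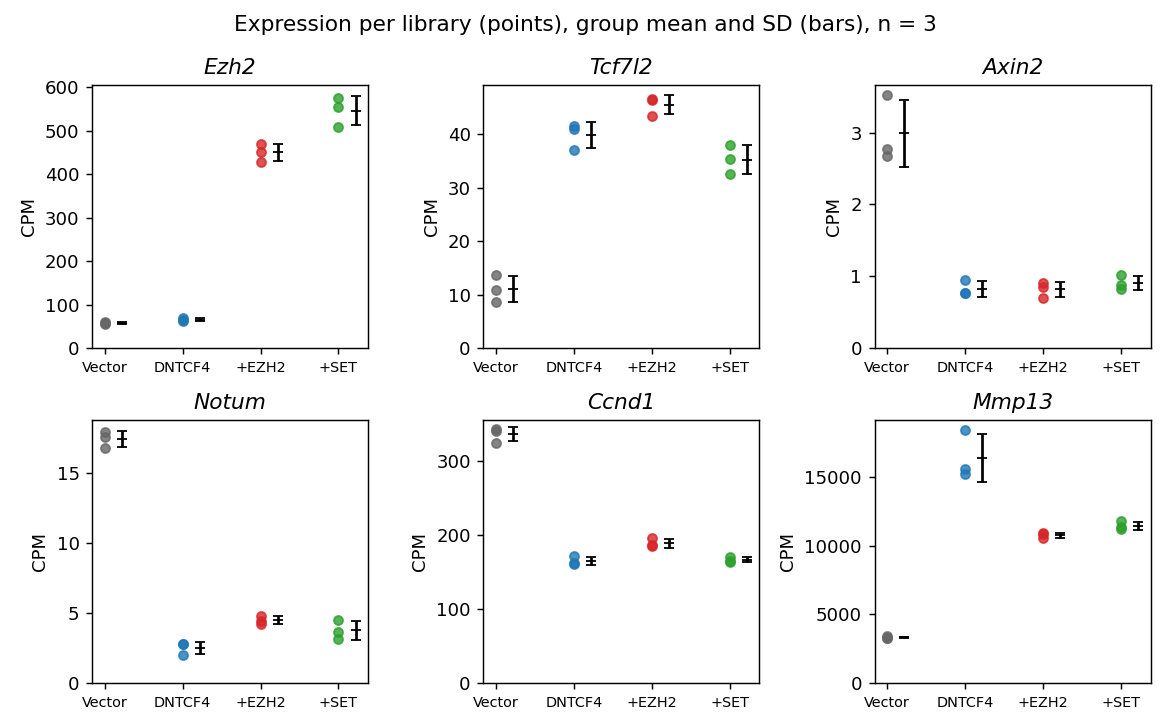
Expression of 6 genes in CPM (linear axes from 0) in each library (points), with the group mean and SD (bars, n = 3) for Vector, DNTCF4, DNTCF4_EZH2 (+EZH2) and DNTCF4_SET (+SET). Ezh2 has means of 57.9 CPM in Vector, 65.4 in DNTCF4, 450 in DNTCF4_EZH2 and 546 in DNTCF4_SET, while Axin2, Notum and Ccnd1 are lower in the 3 groups with DNTCF4 than in Vector; Mmp13, chosen after its values were seen, is higher in them.

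The comparison of DNTCF4 with Vector asks which genes differ in cells that carry the dominant negative construct. Cytokine and chemokine genes rose and many matrix genes fell. Csf3, encoding the granulocyte colony-stimulating factor, went from 2.41 ± 0.128 CPM in Vector to 253 ± 11.6 in DNTCF4, a 104-fold rise (log2 6.71, SE 0.06, adjusted p = 6.68e-19). Il1a, encoding interleukin 1 alpha, rose 203-fold to 74.2 ± 5.46 CPM (adjusted p = 1.06e-15), and the chemokine gene Ccl3 reached 14.4 ± 0.412 CPM with 1222 counts against 2, a ratio of 548 (95% interval 151 to 4530). In the other direction, Col1a2 fell 4.9-fold to 169 ± 3.35 CPM and the Wnt inhibitor gene Notum 6.9-fold to 2.51 ± 0.427 CPM. In all, 8653 of the 15052 genes changed, 4435 higher and 4218 lower in DNTCF4, and 1759 of them by 2-fold or more. The share of higher genes was 51.3%, and it was 47.6% without DNTCF4 replicate 1, 49% without its replicate 2 and 49.6% over the 6 libraries alone. DNTCF4 replicate 1 stood apart from its group, with a chi-square per degree of freedom of 20.7 and 13.1 against the other libraries and 3.34 between these, and without it 9282 genes changed. Reads on the Cre transgene numbered 36, 32 and 15 in the Vector libraries and 6, 4 and 6 in DNTCF4.

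The fixed list of Wnt and beta-catenin targets did not pass its test against the other genes. With fry, which asks whether the list's genes move on balance one way and does not compare them with other genes, it passed (adjusted p = 0.00547). Nearly every list passed fry in this comparison, so that pass is not particular to the Wnt targets. Lists with a median of 0.01 passed too, such as p53 targets (adjusted p = 0.00923) and stem cell genes (adjusted p = 0.0027). Immediate early genes did not (adjusted p = 0.416). Of 18 tested members of the Wnt target list, 6 rose, 7 fell and 5 did not pass. Adjusted over the list alone, 7 rose and 7 fell. Axin2 (chromosome 11, 108920349 to 108950783), a feedback inhibitor of the pathway, fell 3.6-fold from 2.99 ± 0.463 to 0.827 ± 0.109 CPM (log2 -1.85, SE 0.19, adjusted p = 8.53e-07). Notum fell by 2.79 on the log2 scale (SE 0.12, adjusted p = 3.13e-11), the cyclin D1 gene Ccnd1 by 1.03 (SE 0.039, adjusted p = 6.34e-12) and Ccn4 by 1.2 (SE 0.067, adjusted p = 6.34e-10). Against these, Apcdd1 rose 12.6-fold to 2.49 ± 0.158 CPM (adjusted p = 1.5e-09) and Bambi 2.46-fold (adjusted p = 2.43e-05); both encode inhibitors of Wnt or TGF-beta family signalling. Myc lay at 232 ± 28.3 CPM in DNTCF4 and 245 ± 3.43 in Vector (adjusted p = 0.325), and without DNTCF4 replicate 2 it passed the test at a log2 change of -0.15. The list's median log2 change was 0.08 and its mean 0.06, while the camera test pointed down (adjusted p = 0.619). The list's median difference from the Vector mean was -0.12 in DNTCF4 replicate 1, the library that stood apart, and 0.18 and 0.19 in the others; without that library the adjusted p was 0.867. Among the 32 tested ligands, receptors and other parts of the pathway, 12 rose and 10 fell (13 and 10 adjusted over the list alone). The ligand genes Wnt10a and Wnt7b fell 5.17-fold and 2.55-fold and the receptor gene Fzd1 2.03-fold, with a list median of 0.01, a mean of -0.03 and an adjusted p of 0.861.

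Genes of the Polycomb complexes rose slightly in DNTCF4, 12 of 20 members with 1 fall, and the same counts adjusted over the list alone. Epop rose 2.41-fold to 5.01 ± 0.238 CPM, Mtf2 1.55-fold and Ezh1 1.41-fold, and Phf19 was the member that fell (log2 -0.46, adjusted p = 0.0019). The list median was 0.17 (camera adjusted p = 0.0361), which became an adjusted p = 0.152 with an estimated correlation and an adjusted p of 0.0559 without Vector replicate 2. Developmental regulators often marked by H3K27me3, the mark that EZH2 places, went lower as a list: 11 of 20 tested genes fell and 3 rose (12 and 3 adjusted over the list alone), among them Irx3 at 2.97-fold and Wt1 at 2.79-fold, with a median of -0.32 (adjusted p = 0.0361; adjusted p = 0.398 with an estimated correlation). Without DNTCF4 replicate 1 that adjusted p was 0.0814. Against DNTCF4 this list did not pass with either second construct. With EZH2 3 of its 20 tested genes rose and 2 fell (median 0.14, camera adjusted p = 0.378). With SET 4 rose and 2 fell (median 0.08, camera adjusted p = 0.337).

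Cytokine, chemokine and NF-kappaB response genes rose, 23 of 31 tested with 5 falls (24 and 6 adjusted over the list alone), and their median log2 change was 1.3 (adjusted p = 1.39e-08; adjusted p = 0.00329 with an estimated correlation). The neutrophil chemokine gene Cxcl2 rose 52.5-fold to 469 ± 19.2 CPM and the lipocalin gene Lcn2 29.9-fold to 276 ± 9.93. Il1f6 and Vnn3 had no count in the Vector libraries and were at least 33.2-fold and at least 27.2-fold higher in DNTCF4, taking 3 counts over the Vector group as the floor. Interferon response genes went the other way: 24 of 36 fell and 4 rose (26 and 4 adjusted over the list alone), with a median of -0.38 (adjusted p = 4.2e-05; adjusted p = 0.00985 with an estimated correlation). Zbp1 fell 2-fold and Ifit1 2.4-fold. Antigen presentation genes rose in 11 of 18 cases and fell in 4, the same counts adjusted over the list alone, with a median of 0.31 (adjusted p = 0.0155; adjusted p = 0.173 with an estimated correlation). Nlrc5, a regulator of MHC class I genes, rose 2.84-fold to 88.9 ± 2.36 CPM. H2-Q7 and H2-Q6 rose 5.26-fold and 5.32-fold, but they are near copies of each other, so the split of reads between them is uncertain.

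Matrix genes fell. Of 26 tested collagen and matrix genes 18 fell and 5 rose, also adjusted over the list alone, with a median of -0.54 (adjusted p = 0.000165; adjusted p = 0.218 with an estimated correlation). Col1a1 dropped 3.59-fold from 1000 ± 75.5 to 279 ± 21.7 CPM and Col12a1 3.63-fold to 34 ± 0.978. Muscle and cytoskeletal genes fell in 11 of 13 cases and rose in 1 (also adjusted over the list alone), with a median of -0.77 (adjusted p = 8.11e-05; adjusted p = 0.0297 with an estimated correlation), including Myl9 at 14.5-fold and Cnn2 at 2.24-fold. TGF-beta and BMP response genes fell in 15 of 23 cases and rose in 5 (also adjusted over the list alone), among them Ltbp1 at 2.39-fold and Bmp4 at 1.99-fold, with a median of -0.45 (adjusted p = 0.0253; adjusted p = 0.209 with an estimated correlation). That call was lost without DNTCF4 replicate 1 (adjusted p of 0.072). Mesenchymal genes split evenly, with 10 up and 10 down of 24 (11 and 10 adjusted over the list alone): S100a4 fell 7.02-fold, Acta2 4.24-fold and Fn1 2.26-fold to 3860 ± 263 CPM, while Prrx1 rose 4.41-fold and Dcn 4.27-fold to 325 ± 18.2 CPM. Their median was 0.11, their mean -0.12 and the test pointed down (adjusted p = 0.861). Of 22 epithelial genes 7 rose and 1 fell (also adjusted over the list alone; median 0.1, adjusted p = 0.266), among them Elf3, an epithelial transcription factor, 4.39-fold up to 5.73 ± 0.475 CPM. Cdh1, encoding E-cadherin, stood at 0.594 ± 0.187 CPM in DNTCF4 and 0.797 ± 0.33 in Vector (adjusted p = 0.309).

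Myc targets and ribosome biogenesis genes fell in 18 of 30 cases and rose in 3 (19 and 3 adjusted over the list alone), with a median of -0.21 (adjusted p = 0.00489; adjusted p = 0.152 with an estimated correlation), Nop16 by 0.53 and Dkc1 by 0.45 on the log2 scale, whereas Odc1 rose 1.28-fold. G1/S and DNA replication genes rose in 14 of 32 cases and fell in 2 (13 and 2 adjusted over the list alone), among them Cdc45 at 1.34-fold and Mcm4 at 1.27-fold, with a median of 0.11 (adjusted p = 0.0361; adjusted p = 0.152 with an estimated correlation, and 0.0549 without Vector replicate 3). G2/M and mitosis genes rose in 4 and fell in 9 of 30 cases (also adjusted over the list alone; median -0.04, adjusted p = 0.432). Ribosomal protein genes fell in 30 of 37 cases and rose in 1, also adjusted over the list alone, by small steps such as -0.34 for Rplp0 (list median -0.2, adjusted p = 5.01e-05; adjusted p = 0.432 with an estimated correlation). The ferritin heavy chain gene Fth1 rose 2.3-fold and took 3.13% of all counts in DNTCF4 against 1.39% in Vector.

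Olfactory and vomeronasal receptor genes, which are normally silent outside sensory tissue, had a count in 550, 774 and 609 cases in Vector replicates 1 to 3, in 69, 81 and 77 in DNTCF4, in 311, 250 and 241 in DNTCF4_EZH2 and in 325, 472 and 421 in DNTCF4_SET. They summed to 179 ± 102 CPM in Vector and 48.4 ± 4.55 in DNTCF4. The 10 largest falls in DNTCF4 had 0 counts there and included 5 vomeronasal receptor genes or pseudogenes, a family of near copies whose reads cannot be assigned with certainty. Kcnq1ot1, which overlaps Kcnq1 on the opposite strand, was at least 155-fold lower and had been at 5.32 ± 3.77 CPM in Vector. Falls with a smaller spread were those of Inmt, an amine methyltransferase gene, at least 63.9-fold from 2.21 ± 0.175 CPM, and Fam135b, at least 82.9-fold from 2.9 ± 0.374 CPM. Of the genes with a mean under 1 CPM, 504 were lower and 342 higher in DNTCF4, and 448 of the 815 falls of 2-fold or more were of such genes. With limma on the deposited rlog values, 41% of 10642 changed genes were higher, against 51.3% here. The 2 groups' libraries did not overlap in 8923 genes (59.3%), where chance gives 10%.

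**Figure D2:**
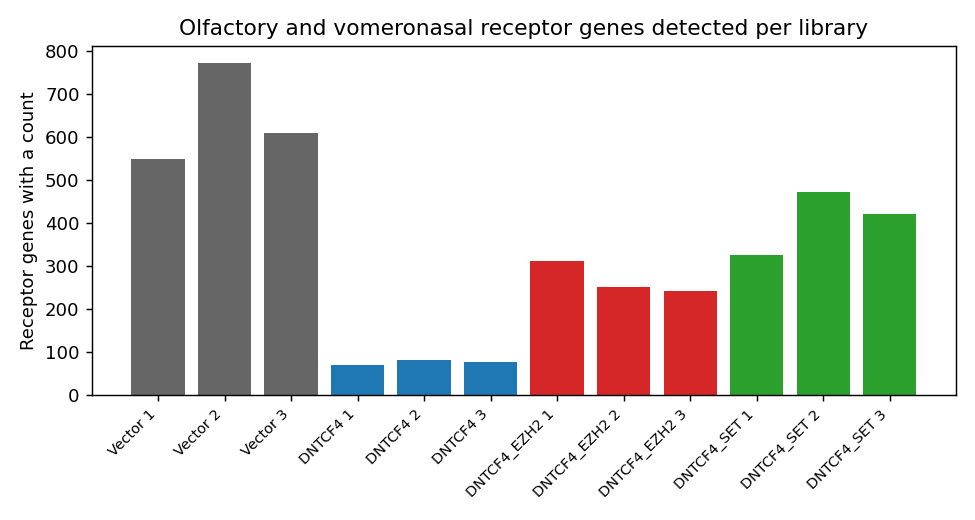
Number of olfactory and vomeronasal receptor genes with a count in each of the 12 libraries. The Vector libraries lie between 550 and 774, the DNTCF4 libraries between 69 and 81, and the libraries with a second construct between 241 and 472.

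The comparison of DNTCF4_EZH2 with DNTCF4 asks what the EZH2 construct changes on the dominant negative background. Interferon response genes fell almost throughout the list. Ifi44 (chromosome 3, 151730922 to 151749960) dropped 13.9-fold from 155 ± 7.42 to 11.2 ± 1.06 CPM (log2 -3.8, SE 0.063, adjusted p = 5.96e-15), and Oasl2 4.3-fold from 158 ± 10.9 to 36.7 ± 1.35 CPM. Genes of mitosis rose, such as Mki67 from 121 ± 4.27 to 194 ± 4.16 CPM, and so did collagen genes, such as Col12a1 from 34 ± 0.978 to 72.5 ± 3.16 CPM. In all 3841 genes changed, 1955 higher and 1886 lower, 261 of them by 2-fold or more. The majority turned without DNTCF4 replicate 2 (49.3% higher) and at 2-fold or more (126 higher and 135 lower, or 55 and 95 with a mean of at least 1 CPM), and without DNTCF4 replicate 1 there were 4477 genes.

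Of 36 interferon response genes 33 fell and 0 rose (34 and 0 adjusted over the list alone), with a median log2 change of -1.48 (adjusted p = 8.09e-43; adjusted p = 6.74e-06 with an estimated correlation). Oas3, encoding an oligoadenylate synthetase, fell 3.76-fold and Gbp3, encoding a guanylate-binding protein, 5.13-fold. The 10 largest falls included the list's members Mx2 at 5.82-fold, Usp18 at 5.73-fold and Oas2 at 6.13-fold. Oas1g, Ifit3, Ifit3b, Slfn4, Trim30d, Phf11d and Gbp3 belong to families of near copies, so their single values are uncertain. Antigen presentation genes fell in 5 and rose in 1 of 18 cases, also adjusted over the list alone, with Tap1 down 1.35-fold (list median -0.03, adjusted p = 0.207).

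Of 30 G2/M and mitosis genes 29 rose (30 adjusted over the list alone), with a median of 0.5 (adjusted p = 1.75e-25; adjusted p = 0.000978 with an estimated correlation). Prc1, a protein of the central spindle, rose 1.62-fold to 120 ± 1.48 CPM, Cenpf 1.56-fold and the mitotic kinase gene Aurka 1.53-fold. G1/S and DNA replication genes rose in 4 and fell in 2 of 32 cases (also adjusted over the list alone; median 0.01, adjusted p = 0.728). Myc targets and ribosome biogenesis genes fell in 22 of 30 cases with 0 rises (26 and 0 adjusted over the list alone), with a median of -0.23 (adjusted p = 4e-11; adjusted p = 0.00315 with an estimated correlation). Odc1, the rate-limiting enzyme of polyamine synthesis, fell 1.64-fold to 590 ± 4.27 CPM. Unfolded protein and stress response genes fell in 17 and rose in 1 of 26 cases (18 and 1 adjusted over the list alone), with a median of -0.27 (adjusted p = 1.3e-09; adjusted p = 0.0011 with an estimated correlation), including the chaperone gene Hspa5 at 1.69-fold and Atf3 at 1.75-fold.

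Collagen and matrix genes rose in 21 of 26 cases and fell in 1 (22 and 1 adjusted over the list alone), with a median of 0.44 (adjusted p = 8.69e-15; adjusted p = 0.0168 with an estimated correlation). Col12a1 rose 2.13-fold, Nid1 1.67-fold and Col1a2 1.46-fold. Mesenchymal genes rose in 12 and fell in 2 of 24 cases (also adjusted over the list alone), with a median of 0.22 (adjusted p = 0.00102; adjusted p = 0.0707 with an estimated correlation), with S100a4 rising 2.12-fold and Dcn 1.43-fold. Basal and myoepithelial genes rose in 7 of 14 cases with 0 falls (also adjusted over the list alone; median 0.26, adjusted p = 0.000364; adjusted p = 0.128 with an estimated correlation), Cnn1 by 1.64-fold. Cholesterol and sterol synthesis genes rose in 14 of 23 cases with 0 falls (15 and 1 adjusted over the list alone), with a median of 0.26 (adjusted p = 1.28e-06; adjusted p = 0.00315 with an estimated correlation), among them Srebf2, their transcriptional regulator, at 1.27-fold. Cytokine, chemokine and NF-kappaB genes fell in 15 and rose in 3 of 31 cases (17 and 5 adjusted over the list alone), with a median of -0.18 (adjusted p = 9.87e-05; adjusted p = 0.00729 with an estimated correlation); Il1a fell 2.02-fold and Cxcl2 1.86-fold to 253 ± 7.3 CPM.

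Wnt and beta-catenin targets changed in 6 of 18 cases, 5 up and 1 down (also adjusted over the list alone). Bambi rose 2.14-fold, Notum 1.78-fold to 4.5 ± 0.271 CPM and Ccnd1 1.15-fold, while Axin2 stood at 0.821 ± 0.106 against 0.827 ± 0.109 CPM (adjusted p = 0.976). Myc was lower by a log2 change of -0.19 (adjusted p = 0.0456), and its call was lost without DNTCF4 replicate 2 (-0.11) or 3 (-0.15) and without DNTCF4_EZH2 replicate 1 (-0.18), 2 (-0.19) or 3 (-0.19). The list median was 0.04 (adjusted p = 0.139), and it passed the threshold without DNTCF4 replicate 3 (adjusted p of 0.0392) and with fry (adjusted p = 0.0193). Ligands, receptors and other parts of the pathway rose in 8 and fell in 2 of 32 cases (also adjusted over the list alone), with a median of 0.09 (adjusted p = 0.0287; adjusted p = 0.201 with an estimated correlation, and 0.0859 without DNTCF4 replicate 1). Sfrp1, encoding a secreted Wnt antagonist, rose 1.68-fold to 27.5 ± 0.347 CPM and Wnt7b 1.41-fold, and the receptor gene Fzd5 fell 1.3-fold. Of 20 Polycomb genes 1 rose, Ezh2, and 4 fell (also adjusted over the list alone), among them Aebp2 by a log2 change of -0.2. The list's median was -0.06, its mean 0.09, and the test pointed down (adjusted p = 0.449). Suz12 differed by -0.05 (adjusted p = 0.744), and by 0.11 without DNTCF4 replicate 1. The rises outside the lists included Hp, encoding the acute phase protein haptoglobin, at 3.49-fold to 27.5 ± 1.31 CPM, the kinase gene Sgk2 at 4.14-fold and Gstt1 at 2.7-fold to 17.2 ± 0.951 CPM.

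The comparison of DNTCF4_SET with DNTCF4 asks the same of the construct labelled SET. Interferon response genes again fell, with Ifi44 down 3.9-fold to 39.8 ± 2.21 CPM (log2 -1.96, SE 0.055, adjusted p = 4.49e-12) and Oasl2 2.61-fold to 60.5 ± 0.894 CPM. Mki67 rose 1.49-fold to 181 ± 5.32 CPM and Col12a1 2.06-fold to 69.9 ± 1.57 CPM. In all 3914 genes changed, 1905 higher and 2009 lower, 304 of them by 2-fold or more. The direction of the majority depended on the setting: 48.7% were higher here, but 54.6% with DESeq2 size factors, 55.3% with DESeq2, 53.9% with limma on the rlog values and 58.9% without Vector replicate 2 and DNTCF4_SET replicate 2. At 2-fold or more 200 were higher and 104 lower, but 50 and 65 among genes with a mean of at least 1 CPM. Below that mean 172 of the changed genes were higher and 50 lower, in a group with more receptor gene reads than DNTCF4. Over the 6 libraries of the comparison alone the count was 2532, 51.2% higher, without DNTCF4 replicate 1 it was 4837, 50.2% higher, and without a filter 4338, 50.8% higher.

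Of the 36 interferon response genes 34 fell and 1 rose (also adjusted over the list alone), with a median of -1.02 (adjusted p = 3.14e-33; adjusted p = 1.82e-05 with an estimated correlation), Oas3 by 2.34-fold and Mx2 by 3.67-fold. G2/M and mitosis genes rose in 25 of 30 cases (26 adjusted over the list alone), with a median of 0.34 (adjusted p = 8.81e-17; adjusted p = 0.00379 with an estimated correlation), Cenpf by 1.5-fold and Ccnb2 by 1.56-fold. G1/S and DNA replication genes fell in 7 of 32 cases with 0 rises (also adjusted over the list alone), Mcm6 by a log2 change of -0.32 and Mcm2 of -0.21, with a median of -0.09 (adjusted p = 0.0101; adjusted p = 0.0428 with an estimated correlation). Myc targets and ribosome biogenesis genes fell in 22 of 30 cases (25 adjusted over the list alone), with a median of -0.25 (adjusted p = 3.02e-11; adjusted p = 0.00379 with an estimated correlation), Nop56 by 1.5-fold. Unfolded protein and stress response genes fell in 16 and rose in 1 of 26 cases (16 and 3 adjusted over the list alone), with a median of -0.18 (adjusted p = 2.3e-06; adjusted p = 0.00379 with an estimated correlation); Ddit3 fell 1.3-fold, and the member that rose was the lipoprotein receptor gene Vldlr at a log2 change of 0.33.

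Collagen and matrix genes rose in 19 and fell in 1 of 26 cases (20 and 1 adjusted over the list alone), with a median of 0.34 (adjusted p = 1.41e-11; adjusted p = 0.0391 with an estimated correlation), including Nid1 and Thbs1, both at 1.48-fold. Mesenchymal genes rose in 12 and fell in 2 of 24 cases (14 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.00052; adjusted p = 0.0495 with an estimated correlation), Dcn by 1.47-fold and Prrx1 by 1.33-fold. Epithelial genes rose in 7 and fell in 1 of 22 cases (8 and 1 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.014; adjusted p = 0.26 with an estimated correlation, and 0.0853 without DNTCF4 replicate 1). Spint1 rose 2.4-fold to 4.35 ± 0.267 CPM and the P-cadherin gene Cdh3 1.77-fold to 3.14 ± 0.0877 CPM, and Krt7 fell 1.3-fold to 47.1 ± 1.1 CPM. Receptor genes summed to 73.6 ± 14.6 CPM in this group against 48.4 ± 4.55 in DNTCF4, and among genes with a mean of at least 1 CPM the epithelial list had an adjusted p of 0.0913. Axon guidance, neural and adhesion genes rose in 13 and fell in 2 of 23 cases (15 and 2 adjusted over the list alone; median 0.2, adjusted p = 3.05e-05; adjusted p = 0.0423 with an estimated correlation), with Robo2, a receptor of axon guidance, 2.71-fold up to 7.64 ± 0.203 CPM.

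Cytokine, chemokine and NF-kappaB genes fell in 12 and rose in 2 of 31 cases (14 and 2 adjusted over the list alone; median -0.12, adjusted p = 0.00946; adjusted p = 0.0423 with an estimated correlation); Lif fell 1.39-fold, and the serum amyloid gene Saa3 rose 1.74-fold to 484 ± 3.56 CPM. Of the 18 Wnt targets 5 rose and 1 fell (also adjusted over the list alone; median 0.11, adjusted p = 0.064), Bambi by 2.19-fold and Apcdd1 by 1.67-fold up and Myc 1.23-fold down. That list passed without DNTCF4 replicate 2 (adjusted p of 0.0412) or 3 (0.0179), without DNTCF4_SET replicate 2 (0.0386) or 3 (0.0338) and with fry (adjusted p = 0.0135). Among the largest rises were Uchl1, encoding a ubiquitin hydrolase, at 3.42-fold to 2.3 ± 0.135 CPM and Sort1, encoding sortilin, at 2.92-fold to 3.05 ± 0.364 CPM. Gli2, a transcription factor of the Hedgehog pathway, rose 2.69-fold to 1.18 ± 0.315 CPM, a call lost without DNTCF4_SET replicate 2 (log2 change 1.2).

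**Figure D3:**
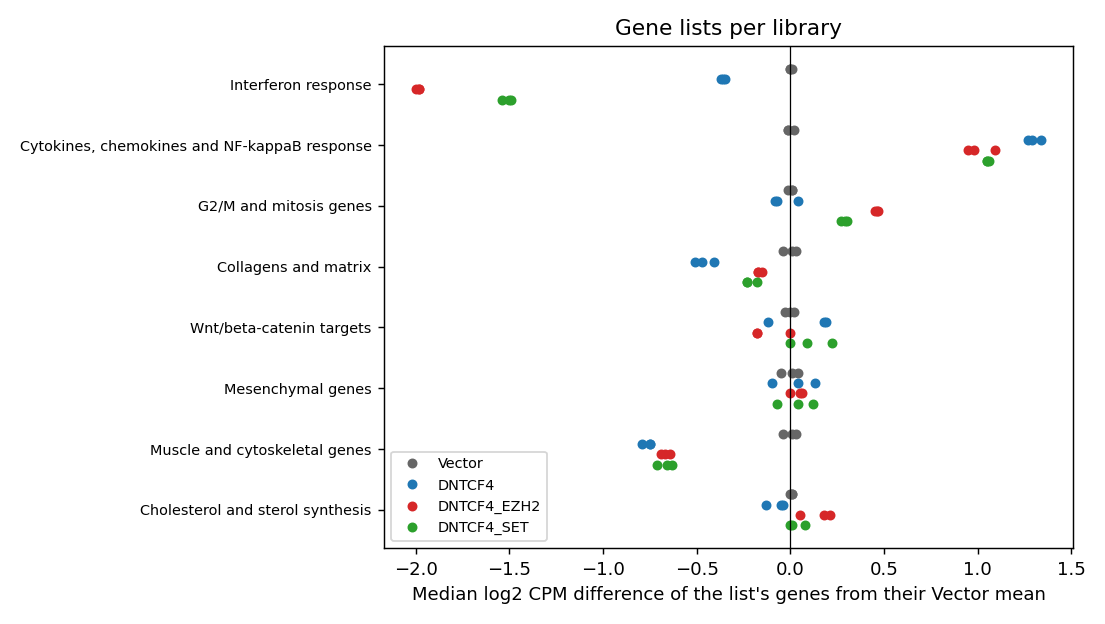
Median over a list's genes of the log2 CPM difference from their Vector mean, for 8 lists (vertical axis) and each of the 12 libraries (points, coloured by group). Interferon response genes lie lowest in DNTCF4_EZH2, then DNTCF4_SET and then DNTCF4, with list medians of the fitted changes against Vector of -1.98, -1.51 and -0.38, and G2/M genes lie highest in DNTCF4_EZH2.

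The direct comparison of DNTCF4_EZH2 with DNTCF4_SET asks where the second constructs differ. Ifi44 was 3.56-fold lower with EZH2 than with SET (log2 -1.83, SE 0.065, adjusted p = 4.39e-10), and Gbp3 2.18-fold lower at 25.5 ± 0.671 against 55.6 ± 1.12 CPM. Neat1, a long RNA that scaffolds nuclear paraspeckles, was 1.74-fold higher at 347 ± 8.8 against 200 ± 1.29 CPM (adjusted p = 7.45e-10). In all 777 genes differed, 451 higher and 326 lower with EZH2, but only 21 by 2-fold or more. The count was 439 without DNTCF4_SET replicate 1, 382 without its replicate 2 and 359 without its replicate 3, and 410, 368 and 375 without DNTCF4_EZH2 replicates 1, 2 and 3 (2177 over the 6 libraries alone). Without both Vector replicate 2 and DNTCF4_SET replicate 2, left out after their receptor gene reads were seen, it was 296. The share of higher genes was 58% here, 47.6% of 912 with DESeq2 and 47.9% of 643 with limma on the rlog values.

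Interferon response genes were lower with EZH2 in 25 of 36 cases and higher in 1 (28 and 1 adjusted over the list alone), with a median of -0.51 (adjusted p = 9.41e-33; adjusted p = 1.93e-05 with an estimated correlation), including Bst2 at 327 ± 4 against 471 ± 7.92 CPM and Rtp4 1.85-fold down. G2/M and mitosis genes were higher in 16 of 30 cases (25 adjusted over the list alone), with a median of 0.19 (adjusted p = 3.93e-16; adjusted p = 0.00494 with an estimated correlation), such as Prc1 at 1.24-fold. G1/S and DNA replication genes were higher in 4 of 32 cases (5 adjusted over the list alone), with a median of 0.08 (adjusted p = 5.37e-06; adjusted p = 0.00596 with an estimated correlation), among them Pole, the catalytic subunit of a replicative polymerase, at 1.19-fold. Cytokine genes were lower in 10 and higher in 1 of 31 cases (11 and 3 adjusted over the list alone; median -0.11, adjusted p = 0.00612; adjusted p = 0.0393 with an estimated correlation), with Il6 1.63-fold down at 12.1 ± 0.794 CPM. Mitochondrially encoded genes were higher in 6 of 13 cases (8 adjusted over the list alone; median 0.18, adjusted p = 3.8e-05; adjusted p = 0.0585 with an estimated correlation), among them mt-Co2 at 169 ± 24.9 against 102 ± 15.1 CPM. Wnt targets differed in 1 of 18 cases, Ccnd1 at 1.14-fold higher (1 higher and 1 lower adjusted over the list alone; median -0.03, adjusted p = 0.976). Ccnd1 did not pass without DNTCF4_EZH2 replicate 3 (log2 difference 0.16) or without DNTCF4_SET replicates 2 or 3 (0.17 and 0.18). Tcf7l2 was 1.29-fold higher with EZH2 (adjusted p = 0.035), and this call was lost when any of the 6 libraries was left out, with log2 differences from 0.32 to 0.42.

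Whether the second constructs turned the DNTCF4 changes back was read from the same tests. Of the 8653 genes changed by DNTCF4 against Vector, 1923 (22.2%) changed in the opposite direction in DNTCF4_EZH2 against DNTCF4 and 793 in the same direction. For SET these counts were 1818 (21%) and 974. Independent lists would give 555.7 genes higher and then lower with EZH2, where 943 were found, and 547.8 lower and then higher, where 980 were found; for SET the counts were 960 against 591.9 and 858 against 533.8. Simulations of unchanged groups drew the counts of the 12 libraries anew around the DNTCF4 means, with 1 spread per gene shared by the groups. They gave a mean of 0 such genes in 5 simulations, which says nothing of opposite calls among genes that do change. That spread may be too small for DNTCF4, whose replicate 1 stood apart (chi-square per degree of freedom of 20.7 and 13.1). The covariance of the log2 changes was -0.0349 for EZH2 and -0.0256 for SET, against simulated -0.0043 and -0.00428, while the correlation across genes was -0.21 and -0.16, nearer to 0 than the -0.52 simulated for both. The 3 shared libraries could not be split into parts of at least 2, so part of the excess may come from them. DNTCF4 minus Vector and DNTCF4_EZH2 minus DNTCF4_SET share no library. Their changes had a correlation of -0.1 and a covariance of -0.00929 (simulated -0.00036 and -1.36e-05), with 301 genes called in opposite and 307 in the same directions. That pair bears on how the EZH2 and SET groups differ, not on whether either turned the DNTCF4 changes back. Receptor genes with a count numbered 644 on average in Vector, 75.7 in DNTCF4, 267 with EZH2 and 406 with SET. Their reads thus also fell and partly returned, and genes lower and then higher may include such reads. Among the genes called higher than in DNTCF4, 81 with EZH2 and 172 with SET had a mean under 1 CPM. Csf3 stood at 253 ± 11.6 CPM in DNTCF4, 172 ± 1.86 with EZH2, 212 ± 4.38 with SET and 2.41 ± 0.128 in Vector. Against Vector, 8688 genes changed in DNTCF4_EZH2 and 8733 in DNTCF4_SET. Of the 1759 genes changed 2-fold or more by DNTCF4, 1585 (90.1%) with EZH2 and 1544 (87.8%) with SET were also called in the same direction against Vector. Among all 1759, called or not, the change was smaller than in DNTCF4 in 64.4% with EZH2 and 59.1% with SET. These genes were chosen for their change against the same 3 Vector libraries, so part of both the shared calls and the smaller changes may come from that choice. Independent lists would share 271 higher and 236.5 lower genes with EZH2, where 868 and 717 were found, and 265.5 and 243.7 with SET, where 848 and 696 were found. The covariance with the DNTCF4 changes over the better expressed genes was 0.337 for EZH2 and 0.347 for SET, against simulated 0.00409 and 0.0041. The EZH2 and SET groups shared 2496 genes changed in the same direction against DNTCF4, and 6 went in opposite directions; independent lists would share 247.4 higher and 251.7 lower genes. Across genes, which are not independent replicates, these changes had a correlation of 0.83, against 0.53 for simulated unchanged groups, and a covariance of 0.0567 against 0.00432. Part of the shared genes may come from the DNTCF4 libraries that both comparisons use.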

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

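The tests of Ezh2 transcript, of genomic DNA in low-count and in better expressed genes and of sequencing depth were chosen after the results were seen. The predictions of the other tests were recorded as written beforehand. Those on interferon response genes and on the chromosome windows still concern patterns picked from the results. The direct comparison of DNTCF4_EZH2 with DNTCF4_SET tests whether these groups differ in their change against DNTCF4, and of what passed that test the lists, the genes with the largest differences and the genes of the constructs are given here.

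The pattern weighed first is the lower interferon response in DNTCF4_EZH2, with a list median of -0.51 against DNTCF4_SET and single genes at -1.83 for Ifi44, -1.13 for Phf11d, -1.12 for Gbp3, -1.08 for Oas1g, -1.07 for Oas2, -1.03 for Ifi27l2a and -1.02 for Usp18. The part of a larger amount of Ezh2 transcript with EZH2 cannot be told apart, because Ezh2 differed by -0.28, higher with SET, but reads of constructs of unknown sequence may be counted on it only in part; protein was not measured. Reads from genomic DNA are argued against by their size, 0.0368 CPM per receptor gene in DNTCF4_SET, where the interferon genes differed by a median of 4.07 CPM. A single library is argued against, since the list median nearest to 0 with 1 library left out was -0.49. What the constructs labelled EZH2 and SET do differently stays open and was not tested.

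The other differences were as follows. In all, 777 genes were called. List medians were 0.19 for G2/M genes, 0.08 for G1/S genes, 0.12 for cholesterol synthesis genes, 0.10 for collagens and matrix, 0.06 for metallothioneins and oxidative stress genes, and 0.18 for mitochondrially encoded genes. They were -0.08 for YAP/TAZ targets, -0.11 for cytokines, -0.06 for unfolded protein response genes and -0.06 for ribosomal protein genes. The calls of collagens (adjusted p = 0.329), YAP/TAZ targets (0.0728), metallothioneins (0.274), mitochondrially encoded genes (0.0585) and ribosomal protein genes (0.668) were lost with an estimated correlation, and that of YAP/TAZ targets also without DNTCF4_SET replicate 1 (adjusted p = 0.0654).

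Genes higher with EZH2 were Adam1a by 1.16, Tcea2 by 1.15, Gsta2 by 1.02, Rab26 by 0.96, Slc6a2 by 0.92, Padi3 by 0.90, Arhgap4 by 0.89, Neat1 by 0.80, Tvp23a by 0.79 and mt-Co2 by 0.72 on the log2 scale. Except for Neat1 and mt-Co2 these had means of at most 2.03 CPM and lost their call when single libraries were left out, and Gsta2 and Adam1a have near copies in the genome. Further genes lower with EZH2 were Chn1 at -1.60, Nat8l at -1.12 and Mcoln2 at -1.06, and of these Nat8l lost its call without any 1 of the 6 libraries and Mcoln2 without any of 5 of them. Tcf7l2 differed by 0.37, and lost its call when any of the 6 libraries was left out (0.32 to 0.42).

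Another pattern is the set of 504 genes with a mean under 1 CPM that were lower in DNTCF4 than in Vector. Deeper sequencing of Vector is argued against, since its mean total was 0.897 times that of DNTCF4. Reads from genomic DNA cannot be told apart from RNA here: these genes had a median ratio of 1.44 between Vector replicate 2 and the other Vector libraries (quartiles 1 and 2.2), where receptor genes of low count in DNTCF4 had 2.89 and a ratio of 1 is the value without such reads. For the 3714 lower genes with a mean of at least 1 CPM the ratio was 0.995 (quartiles 0.961 and 1.03). That argues against such reads as the source of the change of these genes as a set, but does not clear each of them. Kcnq1ot1 at 5.32 ± 3.77 CPM and Gm19212 at 7.04 ± 5.1 CPM in Vector belong to this set. Both had 0 CPM in DNTCF4 and varied widely between the Vector libraries. Of the 815 falls of 2-fold or more, with a ratio of 1.09 (quartiles 0.971 and 1.74), the 367 with a mean of at least 1 CPM had 1.01 (0.956 and 1.09) and the other 448 had 1.5 (1.02 and 2.28). Such reads therefore stay open for the latter and for single genes of the former.

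The last pattern is a pair of chromosome windows whose genes moved together in DNTCF4 against Vector. On chromosome 3 from 140 to 160 Mb (GRCm38) 54 genes had a median log2 change of 0.54, and on chromosome 5 from 0 to 20 Mb 35 genes had -0.44. Chance placement is argued against, since 0% of 1000 shuffles of genes over the 135 windows gave a median as far from 0, the highest being 0.32, although neighbours that are regulated together would escape that test. Reads from genomic DNA, if in excess in Vector, could only bear on the chromosome 5 genes, which were lower in DNTCF4. Such reads are argued against by a ratio of 0.987 (quartiles 0.973 and 1.01) between the Vector libraries, taken over the genes of both windows together. A change of copy number or of clone cannot be told apart from effects of the constructs: 82% of the windows' genes lay on their window's side, but the windows were picked for these genes' medians, and the medians of 0.37 and -0.42 in DNTCF4_EZH2 and 0.49 and -0.40 in DNTCF4_SET rest on the same Vector libraries and the DNTCF4 background.

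For each comparison, 3 libraries against 3 make 10 splits, which are too few for a share under 0.05; in each comparison 1 of the 10, the real split itself, gave as many called genes. The real counts and the highest of the other splits were 8653 and 0 for DNTCF4 against Vector, 3841 and 1 for DNTCF4_EZH2 against DNTCF4, 3914 and 1 for DNTCF4_SET against DNTCF4, 777 and 0 for DNTCF4_EZH2 against DNTCF4_SET, 8688 and 0 for DNTCF4_EZH2 against Vector, and 8733 and 0 for DNTCF4_SET against Vector. Each of the other splits mixes both groups in each part, so a difference between the groups widens the spread within the parts and lowers the calls. Their low counts therefore do not show how many calls chance would give.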

How the results depend on the processing

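The filter at a mean of 1 CPM, the fit without Vector replicate 2 and DNTCF4_SET replicate 2, and the counts of genes that turned back without a Vector, DNTCF4_EZH2 or DNTCF4_SET library were chosen after the data were seen. At 2-fold or more the counts were 1759 for DNTCF4 against Vector, 261 and 304 for DNTCF4_EZH2 and DNTCF4_SET against DNTCF4, 21 between these, and 1753 and 1780 for them against Vector, because the threshold is stricter. Changes of 2-fold or more in both steps, in opposite directions, numbered 92 with EZH2 and 139 with SET. Of the rises of 2-fold or more against DNTCF4, 55 of 126 with EZH2 and 50 of 200 with SET had a mean of at least 1 CPM. Receptor gene reads also fell in DNTCF4 and partly returned, more with SET, so part of these counts may come from such reads. That part was not tested. Over only the 6 libraries compared, DNTCF4_SET against DNTCF4 gave 2532 and DNTCF4_EZH2 against DNTCF4_SET 2177 genes, and without Vector replicate 2 and DNTCF4_SET replicate 2 the last gave 296; the cause was not tested. With 1 library left out the counts ran from 7896 to 9282, 2752 to 4477, 2917 to 4837, 359 to 439, 7930 to 8182 and 7888 to 8312 in the order above, and the genes that turned back from 1409 to 2192 with EZH2 and from 1360 to 2221 with SET; the highest of these in the first 3 comparisons and in both counts that turned back came without DNTCF4 replicate 1, and the cause was not tested. Signs reversed without DNTCF4 replicate 1 for Bmi1 in DNTCF4 against Vector (0.04 with each library, -0.12 to 0.13 with 1 left out) and for Suz12 with EZH2 (-0.05, -0.14 to 0.11) and SET (-0.01, -0.1 to 0.15), none of which passed with each library; the cause was not tested. DESeq2 size factors, DESeq2, limma on rlog values, no filter, the filter at 1 CPM and unrounded counts kept each count of changed genes within 1.5 times; without a filter DNTCF4 against Vector gave 10879 genes, 42.1% higher, and DESeq2 size factors gave 49.5% of 768 higher between EZH2 and SET. List results were followed only for lists that camera called and for the Wnt targets, so no other list could be counted as gained. Of these results, 46 kept their side of the threshold and 36 lost their call with an estimated correlation. Fry kept 77, lost 2 and gained 3, those of the Wnt targets in DNTCF4 against Vector and in both second groups against DNTCF4. Lists not followed passed fry too in DNTCF4 against Vector, such as YAP/TAZ targets (adjusted p = 3.09e-07) and p53 targets (adjusted p = 0.00923). Leaving out 1 library kept 475 of the followed results, lost 12 and gained 5. Of results for named genes, leaving out 1 library kept 2691, lost 170 and gained 40. The replicate number as a block gave 8584, 3713, 3736, 638, 8553 and 8592 genes and 1876 and 1759 that turned back. Of 18 same-number pairs, 4 correlated above 0.1 (-0.342 to 0.305) and 2 of 12 libraries correlated best with their own number, so the numbers were not taken to pair the samples. The same-number pairs of Vector with DNTCF4_SET were all above 0.1 (0.141, 0.305 and 0.125), where other-number pairs of these groups ran from -0.288 to 0.179. A pairing of these 2 groups therefore stays open. Depth limits genes near 1 CPM, where the floor of 3 counts is 0.0882 to 0.127 CPM.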

Other observations

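The test of the run on chromosome 9 was chosen after the result was seen. Of lists not described above, replication-dependent histone genes and metallothionein and oxidative stress genes passed in DNTCF4 against Vector, calls lost with an estimated correlation, while YAP/TAZ targets and hypoxia genes did not pass as lists. Replication-dependent histone genes fell in 8 of 10 cases (also adjusted over the list alone; median log2 change -0.93, adjusted p = 0.0038; adjusted p = 0.267 with an estimated correlation), with H1f2 down 1.91-fold from 72.4 ± 2.24 to 37.9 ± 0.626 CPM. Of 20 metallothionein and oxidative stress genes 15 fell and 5 rose (also adjusted over the list alone; median -0.33, adjusted p = 0.0253; adjusted p = 0.314 with an estimated correlation). Srxn1 fell 1.97-fold, while the metallothionein gene Mt2 rose 2.09-fold and Sod2, encoding the mitochondrial superoxide dismutase, 2.36-fold to 262 ± 5.29 CPM. YAP/TAZ targets fell in 8 and rose in 2 of 22 cases (also adjusted over the list alone; median -0.07, adjusted p = 0.0675), and Ccn2 and Ccn1 parted, the first 2.77-fold down and the second 1.85-fold up to 788 ± 79.9 CPM. Among hypoxia and glycolysis genes 13 rose and 8 fell of 25 (13 and 9 adjusted over the list alone; median 0.12, adjusted p = 0.202), with Ndrg1 up 2.23-fold and Vegfa 1.66-fold to 1250 ± 13.6 CPM. Of markers of other cell types, endothelial ones rose in 5 and fell in 1 of 9 cases (also adjusted over the list alone; median 0.62, adjusted p = 0.234): the VEGF receptor gene Flt1 rose 3.03-fold to 97.1 ± 3.27 CPM, Kdr 3.24-fold to 0.634 ± 0.0309, Cdh5 1.96-fold to 2.09 ± 0.513 and Vwf 1.79-fold to 3.05 ± 0.358. Adipocyte markers rose in 2 and fell in 1 of 6 cases (also adjusted over the list alone; median 0.08, adjusted p = 0.624), the lipoprotein lipase gene Lpl 3.46-fold up to 52.5 ± 1.57 CPM and Cebpa 2.91-fold down to 1.05 ± 0.109. Leukocyte markers rose in 1 of 5 cases (also adjusted over the list alone; median 0.07, adjusted p = 0.468), S100a8 by 4.42-fold to 48.7 ± 3.22 CPM, whereas Cd68 (adjusted p = 0.574) and Csf1r (adjusted p = 0.746) did not pass.

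Further lists passed in the comparisons of the second constructs with DNTCF4. Adipocyte markers rose in 4 and fell in 1 of 6 cases with EZH2 (also adjusted over the list alone; median 0.56, adjusted p = 0.0146; adjusted p = 0.0707 with an estimated correlation) and in 4 of 6 with SET (also adjusted over the list alone; median 0.44, adjusted p = 0.00704; adjusted p = 0.0428 with an estimated correlation). Lpl reached 95.8 ± 1.48 and 86.6 ± 2.22 CPM. Axon guidance, neural and adhesion genes rose in 12 and fell in 2 of 23 cases with EZH2 (15 and 2 adjusted over the list alone; median 0.23, adjusted p = 2.02e-05; adjusted p = 0.0364 with an estimated correlation), among them Robo2 2.43-fold and Sema3e 1.48-fold up. Cholesterol and sterol synthesis genes rose in 9 and fell in 1 of 23 cases with SET (10 and 1 adjusted over the list alone; median 0.11, adjusted p = 0.00202; adjusted p = 0.0338 with an estimated correlation). Immediate early genes fell in 10 of 27 cases with SET (11 adjusted over the list alone; median -0.12, adjusted p = 0.00752; adjusted p = 0.385 with an estimated correlation), such as Dusp5 1.43-fold to 94.3 ± 2.57 CPM. Muscle and cytoskeletal genes rose in 6 of 13 cases with EZH2 (7 adjusted over the list alone; median 0.16, adjusted p = 0.00166; adjusted p = 0.0376 with an estimated correlation) and in 4 with SET (5 adjusted over the list alone; median 0.14, adjusted p = 0.00248; adjusted p = 0.0423 with an estimated correlation), Myh10 by 1.16-fold and 1.18-fold. Basal and myoepithelial genes rose in 6 of 14 cases with SET too (also adjusted over the list alone; median 0.23, adjusted p = 0.00052; adjusted p = 0.116 with an estimated correlation), Lamb3 by 1.18-fold. Also with SET, TGF-beta and BMP response genes rose in 5 and fell in 2 of 23 cases (6 and 2 adjusted over the list alone; median 0.12, adjusted p = 0.0211; adjusted p = 0.131 with an estimated correlation, and 0.0551 without DNTCF4_SET replicate 1), Ltbp1 by 1.27-fold. YAP/TAZ targets rose in 6 and fell in 1 of 22 cases with SET (also adjusted over the list alone; median 0.09, adjusted p = 0.0146; adjusted p = 0.0781 with an estimated correlation, 0.0604 without DNTCF4 replicate 1 and 0.0551 without DNTCF4_SET replicate 1), Tgfb2 up 1.47-fold and Ankrd1 down 1.19-fold. With EZH2, metallothionein and oxidative stress genes rose in 9 and fell in 2 of 20 cases (also adjusted over the list alone; median 0.11, adjusted p = 0.00902; adjusted p = 0.201 with an estimated correlation), Gsta4 by 1.37-fold. Ribosomal protein genes fell in 3 of 37 cases with EZH2 (1 adjusted over the list alone; median -0.07, adjusted p = 0.0287; adjusted p = 0.621 with an estimated correlation, 0.177 with fry, 0.053 among genes of at least 1 CPM and 0.474 without DNTCF4 replicate 2).

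On chromosome 9 (GRCm38, 6928503 to 8042823) 19 neighbouring tested genes from Dync2h1 to Cfap300 had a median of 168 CPM, where 20 flanking genes had 20.1 and all tested genes 20.9. Of 14622 windows of as many neighbours elsewhere 0% reached that median, but the run was delimited after its high levels were seen, so chance placement of highly expressed genes cannot be told apart. Of the 19 genes 7 lay below the median of all tested genes, from Mmp7 at a mean of 0.315 CPM to Gm45494 at 2.78. The run holds Yap1, Birc2 and Birc3 and the matrix metalloproteinase genes Mmp13 and Mmp3, picked after their values were seen. Mmp13 was at 3320 ± 56 CPM in Vector and 16400 ± 1800 in DNTCF4. The run's other genes above that median did not all move this way. Mmp12, Mmp1b, Mmp3 and Mmp10 rose in DNTCF4 against Vector (log2 changes 4.1, 0.92, 1.84 and 0.83). Dync2h1, Dcun1d5, Tmem123, Birc3, Yap1 and Cfap300 fell (-0.38, -0.48, -0.66, -0.13, -0.39 and -0.49). Birc2 did not pass (0.02, adjusted p = 0.84 in edgeR's test). Why these neighbours had such levels was not tested.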
